A study of Mus musculus and Homo sapiens with 61 samples.

How the data were processed

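The series holds 61 samples: mouse liver RNA (15), mouse ChIP-seq for Foxa2 (6) and lamin B1 (8), human liver ChIP-seq for Foxa2 (9) and lamin B1 (9), and H3K9me3 and input samples, which were not analysed here. The submitters' processing notes name BWA 0.7.12, Picard 1.134, SICER, STAR, RSEM and edgeR, with builds mm10 (GRCm38) and hg19 (GRCh37). The caller of the Foxa2 peaks and the way replicates were combined are not given in the sources used here.

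The RNA values are 2 tables made by the authors with edgeR, 1 per diet duration. Per the file headers they hold a log2 fold change, an average expression on the log2 scale (logCPM), a likelihood ratio, a p-value and an adjusted p-value per gene. Every listed gene has an adjusted p under 0.05. The likelihood ratio in the deposited tables is a test statistic, an other unit, and was used only for implied standard errors. No score is given in the deposited region lists, which carry a chromosome, a start and an end for each region. The deposited lists hold no read counts, so depth per sample and the precision it gives are unknown. No new test between animals was made, and no library was left out in turn.

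The direction of the fold change is not written in the tables and was read as Western over normal diet. Sterol synthesis genes are known to fall when cholesterol is eaten, and they are lower under this reading, so their fall is not a result of its own. Because a table ends at its threshold, the number of genes tested was recovered from adjusted p times rank over p, among genes with p above 0.0001. This gave 10370 genes at 8 weeks, where 74.2% of ranks were whole numbers within 0.02, and 22091 at 12 weeks, where 70.9% were. An adjustment over the members of a list alone cannot be formed, since p-values of members not called are not in the tables.

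A total of 19 gene lists were written before the data were examined, as were the comparisons, their tests and most of the alternative settings. Membership among called genes was tested against 21887 protein-coding genes with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment over 38 tests. Genes named are the 12 largest rises and 12 largest falls per table, leaving out predicted genes and immunoglobulin segments, and up to 6 called members per list. For domains they are the 5 longest per direction. Some genes within this rule are not reported here. Another 5 lists were chosen after the tables were seen and stand in the closing section: interferon-stimulated genes, glutathione transferases, skeletal muscle, mitochondrial genome protein genes and neutrophil markers.

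Foxa2 peaks were shared when they overlapped by at least 1 bp. A peak lay in a domain when its midpoint did. Chance was taken from 1000 circular rotations along each chromosome, and the smallest p they can give is 0.001. Shares have Wilson 95% intervals. Specific and shared peaks were compared by Fisher's exact test over sequence covered by normal domains only (lost), by the other group's domains only (gained) or by both (kept), with 1 Mb bins resampled 1000 times as a check on neighbouring peaks. Genes were called near a peak within 20 kb of the gene's span, and in a domain by gene midpoint. The plan had named the transcription start site, but the annotation used gives no strand. Human regions were compared by position only. Adjustment covered 12 tests for peaks in lost, gained and kept sequence, 12 each for genes near peaks and in domains, and 6 for rotations.

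Alternatives tried were a stricter adjusted p, a log2 fold change minimum of 1, other backgrounds, half-covered peaks or peaks within 500 bp, windows of 5 and 100 kb, merged or longer domains and autosomes only. Others chosen after the data were seen were resized peaks, equal list lengths, removal of 1 Mb bins with at least 10 peaks, other comparison groups and a gene midpoint window of 50 kb.

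Functions were tested on simulated data. Interval overlaps disagreed with a direct count in 0 of 50 pairs of lists. The rotation test gave p under 0.05 in 8 of 100 lists without enrichment and in 40 of 40 lists with 3% of peaks placed in domains. The number of genes tested was recovered in 5 of 5 tables at each of 2 sizes, and Fisher's test passed 7 of 400 random lists. Computing used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.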

Results

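The study fed mice a normal chow or a Western diet and profiled the liver by RNA sequencing and by chromatin immunoprecipitation with sequencing (ChIP-seq), and ran the ChIP-seq arm on human liver as well. The Western diet carried 42% of its energy as fat with 0.1% cholesterol, and the drinking water held 23.1 g/L fructose and 18.9 g/L glucose, a regimen that fills the liver with fat. Mice were killed after 8 or 12 weeks of diet. RNA comes from 4 normal-diet and 4 Western-diet livers at 8 weeks, and from 4 normal-diet and 3 Western-diet livers at 12 weeks. The labels give 1 of the 8-week Western-diet mice the age of the 12-week mice, 5 months in place of 4, and its part in the 8-week values cannot be separated here. Foxa2, a forkhead transcription factor that opens chromatin at liver genes, was mapped in 2 livers per diet group. Lamin B1 is a protein of the meshwork under the inner nuclear membrane, and its ChIP signal is used to mark lamina-associated domains. It was mapped in 4 normal-diet livers, 2 after 8 weeks of Western diet and 2 after 12 weeks. The normal-diet lists mix ages: the Foxa2 list pools 1 mouse of 4 and 1 of 5 months, and the lamin B1 list 2 mice of the 8-week and 2 of the 12-week group, so each Western list is compared with a control of mixed age. The human arm has 3 livers each without disease, with mild non-alcoholic fatty liver disease (NAFLD) and with severe NAFLD, for both proteins. The deposited RNA values are tables of genes called at 8 and at 12 weeks, and the deposited ChIP values are lists of regions, 1 list per group and protein, so no value per animal or person enters the comparisons. The read depth behind the lists and tables is unknown.

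The first question was which liver transcripts differed after 8 weeks of Western diet. All 25 members of the cholesterol synthesis and uptake list had the same sign in the authors' deposited table, read here as lower on the Western diet. The table does not state the direction of its fold change. It was read as Western over normal diet at both times from the known fall of sterol synthesis genes when cholesterol is eaten, so their fall is assumed here and not found, and every other direction in RNA rests on it. Sqle, which encodes squalene epoxidase (GRCm38 chromosome 15, 59315092 to 59331193), fell by 4.82 on the log2 scale in the authors' deposited table, with an adjusted p of 7.7e-80. Idi1, an isomerase of the isoprenoid branch, had a log2 fold change of -4.36 in the authors' deposited table, Cyp51 one of -3.06 and Hmgcs1 one of -3.03. Nsdhl and Msmo1, later steps of the same pathway, stood at -3.07 and -3.06 in the authors' deposited table. Abcg5 and Abcg8, the paired transporters that pump sterols out of hepatocytes, rose by 1.89 and 1.63 in the authors' deposited table, as did the cholesterol exporter Abca1 by 0.62.

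In total 395 genes were called at 8 weeks in the authors' deposited table, 206 higher and 189 lower on the Western diet, and the median absolute log2 fold change was 0.92. Only genes at an adjusted p under 0.05 are listed, so a gene absent from a table may have been tested without passing or not tested. At an adjusted p under 0.01 the count was 254, and 173 genes had an absolute log2 fold change of at least 1.

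Genes of fatty acid and triglyceride synthesis went both ways at 8 weeks. Of 25 members, 5 were higher and 4 lower in the authors' deposited table. Lpin1, Pklr, Scd1 and Srebf1 rose by 1.96, 1.52, 1.44 and 0.97 on the log2 scale, and Acss2 and Acacb were at -1.45 and -1.11 in the authors' deposited table. Lipid uptake and lipid droplet genes were higher in 5 of 25 cases: Lpl at 2.02, the droplet coat gene Plin4 at 1.65, Fabp2 at 1.59, the fatty acid translocase gene Cd36 at 1.41 and Apoa4 at 1.29 in the authors' deposited table. The ketohexokinase gene Khk rose by 0.68 in the authors' deposited table, and the insulin receptor substrate genes Irs2 and Irs1 fell by 1.16 and 0.67. Xenobiotic metabolism genes were lower in 8 of 28 cases, among them the glutathione transferase genes Gsta2 at -1.62 and Gstm3 at -1.54 and the cytochrome P450 gene Cyp2c55 at -1.30 in the authors' deposited table.

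Some macrophage markers were already higher at 8 weeks. Of 24 markers, 6 rose in the authors' deposited table, led by Mpeg1 at 1.58 and Cd5l at 1.42, with the Kupffer cell lectin Clec4f at 0.59. Acute phase genes rose beside them: Orm3 at 2.77, Lcn2 at 2.73, Saa2 at 1.85 and Saa1 at 1.81 in the authors' deposited table, while the iron hormone gene Hamp was lower at -1.02. None of the 21 lymphocyte and antigen presentation markers was listed at 8 weeks, and 2 of 33 extracellular matrix genes were, Col14a1 at 0.74 and Bgn at 0.47 in the authors' deposited table. Saa and Orm genes are near-identical copies, so their reads can be shared.

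Among single genes, Ntrk2, a neurotrophin receptor gene, rose most at 8 weeks, by 5.83 on the log2 scale in the authors' deposited table. Fmn2 followed at 4.75, then the glutathione-degrading enzyme gene Chac1 at 4.19, Moxd1 at 3.73, Obp2a at 3.30 and the cytokine signalling inhibitor Cish at 3.06 in the authors' deposited table. The other 6 of the 12 largest rises were Stap1, Cacna2d3, Themis, Lrtm1, Tmem28 and Gadd45g, from 3.28 to 2.81 in the authors' deposited table. Among the 12 largest falls were 4 skeletal muscle transcripts: Acta1 at -7.68, Myh4 at -6.17, Ttn at -6.12 and Atp2a1 at -5.81 in the authors' deposited table. Tcf24 at -6.06, Cyp2a4 at -3.90, Chrna4 at -3.51 and the secreted peptide gene Enho at -3.12 were the falls in the authors' deposited table outside muscle and sterol synthesis. Cyp2a4 has a close paralog, so its reads can be shared.

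Set against 21887 annotated protein-coding genes, 11 of the 19 lists held more called genes than chance at 8 weeks (two-sided Fisher's exact test, Benjamini-Hochberg over 38 list tests). The cholesterol list gave an adjusted p of 2.4e-43, fatty acid and triglyceride synthesis 3.0e-09, xenobiotic metabolism 1.5e-07, acute phase 4.7e-06, macrophages 1.0e-05 and lipid droplets 0.00019. This background includes genes the liver does not express. With the 10370 genes tested, a number recovered from the table's own p-values, 7 lists held: fatty acid oxidation, sterol transport, nuclear lamina and male-biased genes no longer passed (adjusted p = 0.18, 0.067, 0.19 and 0.067).

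The other lists had few called members at 8 weeks. Of 31 fatty acid oxidation genes 3 were lower in the authors' deposited table: Abcd2 at -2.68, Acot3 at -2.18 and Pdk4 at -1.17. Male-biased genes had Cyp4a12b at 1.55, C6 at 1.03 and Susd4 at -0.63 in the authors' deposited table, and 2 of 20 female-biased genes were lower (adjusted p = 0.07). Glucose metabolism passed with 4 of 17 members called (adjusted p = 0.00049), and still did with the genes tested as background (adjusted p = 0.0074), while cell cycle genes, with Gadd45g and Cdkn1a higher, did not (adjusted p = 0.054). Chac1 was the only 1 of 16 endoplasmic reticulum stress genes listed (adjusted p = 0.31). No hepatocyte identity, clock, or endothelial, stellate and cholangiocyte gene was listed.

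After 12 weeks the question was the same, and the list of genes was longer and more often higher. The authors' deposited table held 761 genes, 512 higher and 249 lower, with a median absolute log2 fold change of 1.59. It reached lower-expressed genes than the 8-week table: its lowest average expression was -1.28 on the table's log2 expression scale, against 2.12 at 8 weeks in the authors' deposited table. Of the 761 genes, 519 lay at or above the 8-week minimum, 305 of them higher and 214 lower in the authors' deposited table. Below it, 207 were higher and 35 lower in the authors' deposited table. A count under an adjusted p of 0.01 left 376 genes.

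Lipid storage genes were among the rises at 12 weeks. Cidea, which encodes a protein that fuses lipid droplets (chromosome 18, 67343564 to 67367794), rose by 9.32 on the log2 scale with an adjusted p of 2.9e-16 in the authors' deposited table. Its relative Cidec rose by 4.30, Apoa4 by 2.63, Fabp4 by 2.49, Fabp2 by 2.28 and Lpl by 1.99 in the authors' deposited table. Of the 25 lipid droplet and uptake genes, 9 were listed and all 9 were higher in the authors' deposited table. Fatty acid and triglyceride synthesis had 8 listed members, and each was higher in the authors' deposited table. The patatin-like phospholipase genes Pnpla5 and Pnpla3 rose by 6.65 and 5.19, the monoacylglycerol acyltransferase gene Mogat1 by 4.24 and the desaturase gene Scd1 by 2.31 in the authors' deposited table. Elovl6 and Thrsp each stood at 1.44 in the authors' deposited table. Slc2a4, the insulin-regulated glucose transporter gene of muscle and fat, rose by 6.86 in the authors' deposited table.

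Of the sterol synthesis list 20 of 25 members were called at 12 weeks, all 20 lower in the authors' deposited table under the same reading. Sqle was at -4.68, Idi1 at -3.65, Msmo1 at -2.56 and Cyp51 at -2.53 in the authors' deposited table. Abcg5 and Abcg8 were again higher, at 1.96 and 1.04 in the authors' deposited table, while the transporters Slco1a4 and Abcc4 and the bile acid enzyme gene Cyp7b1 were lower, at -1.83, -1.68 and -1.53.

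Immune and matrix genes rose together at 12 weeks. Macrophage and monocyte markers were higher in 10 of 24 cases, including Gpnmb at 4.41, the monocyte chemokine gene Ccl2 at 3.46, Trem2 at 3.25, Lgals3 at 2.64 and Ccr2 at 2.22 in the authors' deposited table. Of these 10 markers, 4 lay at or above the 8-week expression minimum, as did 6 of the 10 matrix genes below. Extracellular matrix genes were higher in 10 of 33 cases: Mmp12, a macrophage elastase gene, at 5.34, Timp1 at 3.79, and the fibrillar collagen genes Col1a1 at 2.58, Col3a1 at 1.90 and Col1a2 at 1.71 in the authors' deposited table. Antigen presentation genes joined them, with H2-Eb1 at 2.49, H2-Aa at 2.24, H2-Ab1 at 2.15 and Cd74 at 1.79, and the lymphocyte chemokine gene Ccl5 at 2.74 in the authors' deposited table. None of Cd3e, Cd4, Cd8a or Ms4a1 was listed. Acute phase genes were higher in 6 of 21 cases, with Lcn2 at 4.13, Saa2 at 2.85 and Saa3 at 2.14 in the authors' deposited table. Of the endothelial, stellate and cholangiocyte markers, Lyve1 at 2.05 and Spp1 at 1.42 were listed in the authors' deposited table.

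Hepatocyte lists went both ways. Xenobiotic metabolism had 4 of 28 members higher and 5 lower (list adjusted p = 1.0e-06): the cytochrome P450 genes Cyp2b9 and Cyp2b13 rose by 5.65 and 3.20, while Cyp2b10 was at -2.18 and Cyp3a11 at -1.53 in the authors' deposited table. These Cyp2b genes are close paralogs whose reads can be shared, and Cyp2b9 and Cyp2b13 also stand in the list of female-biased liver genes. Of 3 female-biased genes called at 12 weeks, 2 were higher and 1 lower, and none lay at or above the 8-week expression minimum. Male-biased genes were lower in 4 of 20 cases, among them Serpina1e at -3.04 and Hsd3b5 at -1.15 in the authors' deposited table (list adjusted p = 0.0087). The clock genes Cry1, Clock and Cry2 were lower, at -1.10, -0.81 and -0.80 in the authors' deposited table. Foxa3, the only one of 19 hepatocyte identity genes listed, was at -1.12 in the authors' deposited table, and Foxa2 itself was listed at neither time. Lbr, the lamin B receptor gene, was lower at both times, at -0.65 at 8 weeks and -0.89 at 12 weeks in the authors' deposited tables. Lmnb1 was listed at neither. The nuclear lamina list had 2 called genes at 8 weeks, 1 higher and 1 lower. Glucose metabolism had 5 of 17 members called at 12 weeks (list adjusted p = 0.00049), with Irs2 at -1.83 and Irs1 at -1.24 in the authors' deposited table. Fatty acid oxidation had 3 genes higher at 12 weeks, Vnn1 at 2.0, Acot2 at 1.58 and Acaa1b at 1.09 in the authors' deposited table (list adjusted p = 0.12). Cdkn1a at 2.72 and Asns at -2.29 were the only cell cycle and endoplasmic reticulum stress genes in the authors' deposited table (list adjusted p = 0.51 and 0.50).

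The largest rises also took in H3c14 at 7.88, A4gnt at 7.53, Ly6d at 7.12, Sptlc3 at 6.34, Ubd at 6.13, Mas1 at 6.07, Mpped1 at 6.0, S100a4 at 5.81 and the neutrophil gene S100a9 at 5.80 in the authors' deposited table. Outside sterol synthesis the largest falls were Moxd1 at -5.05, Spatc1l at -4.84, Nuggc at -4.54, Adgrf1 at -4.45, Tuba8 at -4.32, Slc13a2 at -4.18 and Enho at -3.69 in the authors' deposited table. Klhl33, Tafa2 and Rab11fip4 closed the 12, from -3.61 to -3.07 in the authors' deposited table. Spatc1l, Nuggc, Adgrf1, Tuba8, Slc13a2, Klhl33 and Tafa2 were little expressed. Their logCPM ran from -0.86 to 1.46 in the authors' deposited table, below the 8-week minimum of 2.12. S100a9 among the rises lay below it too, at -0.54 in the authors' deposited table. At 12 weeks 13 of the 19 lists held more called genes than chance, and 11 did with the 22091 genes tested. Female-biased and clock genes were those that no longer passed (adjusted p = 0.057 for each). The 22091 genes outnumber the 21887 protein-coding genes, so, unlike at 8 weeks, this background does not narrow the test to expressed genes. The cholesterol list gave an adjusted p of 2.7e-24, macrophages 2.3e-08, lipid droplets 4.5e-07, extracellular matrix 4.7e-07, fatty acid and triglyceride synthesis 4.6e-06, acute phase 0.00017 and antigen presentation 0.0013.

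**Figure D1:**
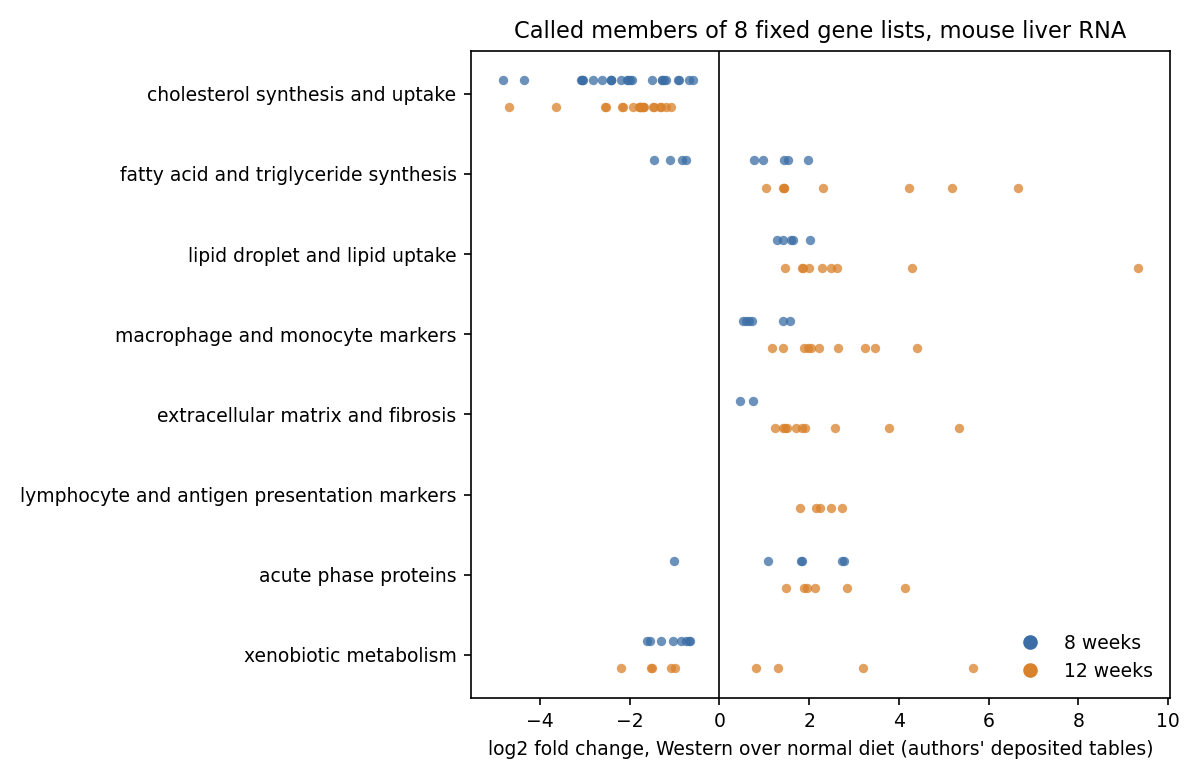
Each point is 1 called gene of 1 of 8 fixed lists, placed by its log2 fold change on Western over normal diet from the authors' deposited tables, at 8 weeks (blue) and 12 weeks (orange). Cholesterol synthesis lies below 0 at both times, down to -4.82, and the matrix and macrophage points reach 5.34 and 4.41 at 12 weeks.

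Whether both times called the same genes was tested next. Both authors' deposited tables listed 148 genes in common, of which 142 had the same sign (95.9%; two-sided exact binomial test, p = 7.7e-35). By direction, 76 genes were higher at both times against 4.82 by chance (odds ratio 28.5, 95% interval 21.1 to 38.4, Fisher's exact p = 1.2e-70), and 66 were lower at both against 2.15 by chance (odds ratio 63.1, 95% interval 45.2 to 88.0, p = 1.2e-81). Among genes at or above the 8-week expression minimum, with the 10370 genes tested at 8 weeks as background, these odds ratios were 24.7 and 34.2. The normal-diet mice of the 2 comparisons were separate. The direction at both times was set from the sterol genes, so the agreement of the 20 called at both was assumed. Genes were counted as independent, so these p-values do not measure agreement between mice. Genes that rose at both times included Ntrk2, Stap1, Lcn2, Scd1 and Cd36. The 6 genes of opposite sign, named here because they are few and chosen after their values were seen, were Moxd1, Scara5, Foxq1, Eif4ebp3 and Fkbp5, higher at 8 weeks and lower at 12 weeks, and Gstm3, lower and then higher. Of the genes called at 12 weeks, 613 were not called at 8 weeks.

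Lamin B1 domains were compared to ask whether the diet moved the lamina along the genome. At 8 weeks their extent matched the normal diet closely: 1508 domains covered 316.5 Mb, against 1386 domains over 317.9 Mb on normal diet (mm10). The lists shared 255.8 Mb, which is 80.5% of the normal-diet sequence, with a Jaccard index of 0.676. Outside the shared part, 243 normal-diet domains had no overlap at 8 weeks and 290 domains were new. The longest normal-diet domain lost at 8 weeks lay on chromosome 7, 117370001 to 117659999, over Xylt1. Next came chromosome 11, 106520001 to 106769999, over Tex2, Pecam1, Milr1 and Polg2, and chromosome 15, 38160001 to 38409999, over Odf1 and Klf10. Among the 5 longest gained at 8 weeks were chromosome 14, 46860001 to 47129999, over Samd4, chromosome 14, 118480001 to 118719999, over Abcc4, and chromosome 8, 109520001 to 109759999, over 9 protein-coding genes that include Hp, the haptoglobin gene.

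After 12 weeks of Western diet the list was far shorter, with 141 domains over 17.6 Mb and a longest domain of 290 kb, against 2470 kb on normal diet. It covered 5.27% of the normal-diet domain sequence. Of its 141 domains, 136 touched a normal-diet domain, and 95.1% of its bases lay inside one. The longest normal-diet domains absent at 12 weeks were chromosome 4, 152760001 to 154839999, which spans Prdm16 and Trp73, and chromosome 8, 119930001 to 121399999, which spans Irf8, Foxf1 and Foxc2. Chromosome 7, 143880001 to 145339999, with Ccnd1 and Fgf15, was next. The 5 domains gained at 12 weeks included chromosome 19, 37230001 to 37379999, over Ide and Kif11, and chromosome 3, 106120001 to 106259999, over the chitinase-like genes Chia1, Chil3 and Chil4. Replicates were combined in each list by a step not given in the sources used here, so these differences have no replicate error.

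The mouse domains lay in gene-dense sequence. Normal-diet domains held 17.9 protein-coding gene midpoints per Mb against 6.79 outside, 1.94 times the mean of 1000 rotations of the genes along their chromosomes. The ratio was 1.95 at 8 weeks and 2.90 at 12 weeks, and each gave a permutation p = 0.001, the smallest value that the rotations allow. Whether the listed regions touch the lamina was not tested by another measure.

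**Figure D2:**
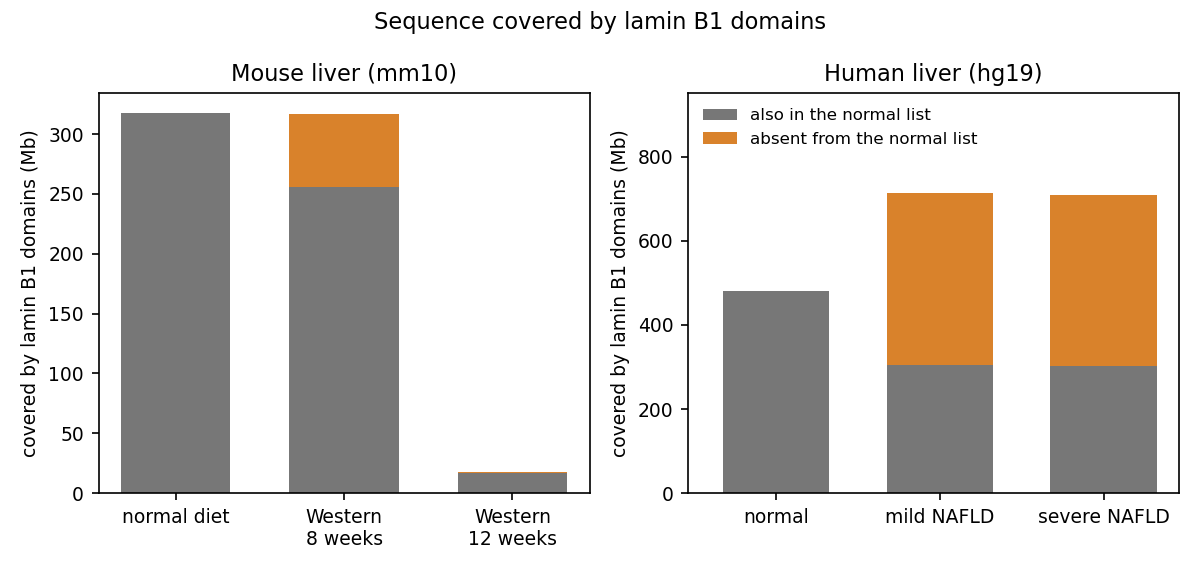
Bars give the sequence in Mb covered by lamin B1 domains in each pooled list, split into sequence also covered in the normal list (grey) and not (orange), for mouse diets and human groups. The 12-week list covers 17.6 Mb against 317.9 Mb on normal diet, and the mild and severe lists cover 714.5 and 709.6 Mb against 479.8 Mb.

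Foxa2 binding was compared in the same way. The lists held 6985 peaks on normal diet, 5189 after 8 weeks and 11191 after 12 weeks of Western diet. Most peaks stood in 1 list. Of the 8-week peaks, 991 (19.1%, Wilson 95% interval 18.1 to 20.2) overlapped a normal-diet peak by at least 1 bp, and of the 12-week peaks 2461 (22.0%, 21.2 to 22.8) did. Chance rotation gave means of 5.64 and 11.7 peaks. In the other direction 14.1% of normal-diet peaks were found at 8 weeks and 35.2% at 12 weeks, 818 were found at both times and 4363 at neither. Of the 12-week peaks 8.42% overlapped an 8-week peak. The 12-week list is the longest, and with each list cut to the first peaks, as many as the shortest holds, its shares were 38.0% with normal diet and 16.6% with 8 weeks. Intervals cover counting error only.

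Sharing depended on the place in the list. With each list split into 10 parts in deposited order, 87.9% of the first part of the 12-week list was shared with normal diet and 5.72% of the last. At 8 weeks the shares were 79.0% and 3.28%. The order of the lists is not documented and goes with length, longer peaks coming first (Spearman correlation of position with length -0.542, -0.575 and -0.565 in the normal, 8-week and 12-week lists). With every peak set to 200 bp the shares were 84.2% and 5.72% at 12 weeks and 67.2% and 3.28% at 8 weeks. The lists also differ in form: normal-diet peaks are at least 200 bp long, while those of the Western-diet lists go down to 1 bp.

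**Figure D3:**
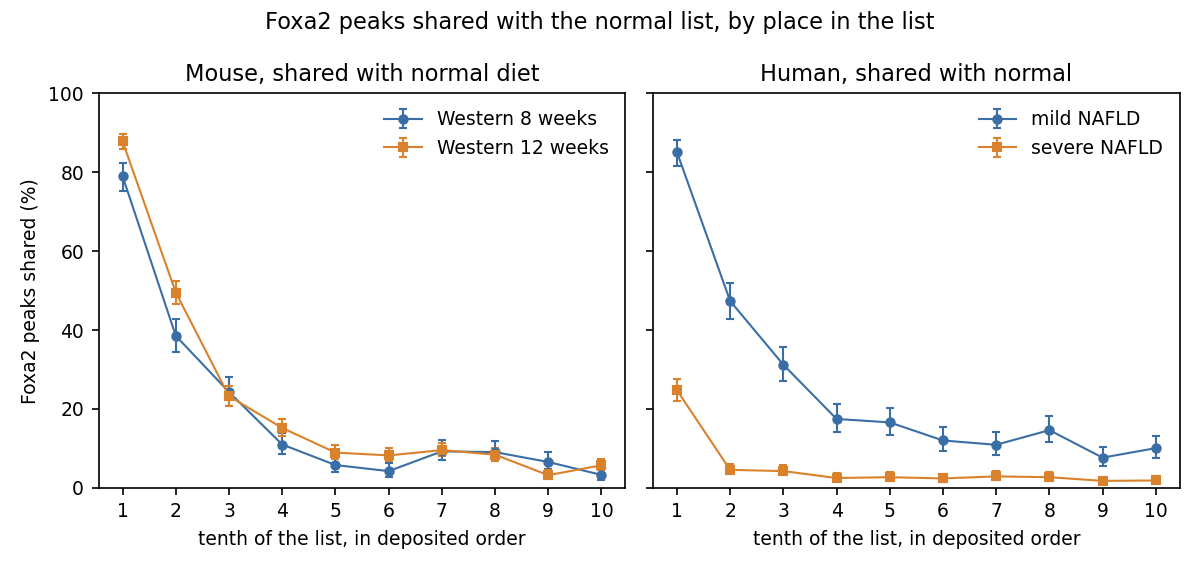
Points give the percent of Foxa2 peaks that overlap a peak of the normal list, for each of 10 equal parts of a list in deposited order, with Wilson 95% intervals, in mouse (left) and human (right). Sharing starts at 79.0% and 87.9% in the mouse lists and ends at 3.28% and 5.72%; in severe NAFLD it starts at 24.8%.

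Foxa2 peaks were then placed against the domains of the same diet. On normal diet 1066 of 6985 peaks (15.3%) had their midpoint in a domain, 1.21 times the rotated mean (adjusted p = 0.0075). At 8 weeks 13.4% did, a ratio of 1.10 that was not past the threshold (adjusted p = 0.18). At 12 weeks 149 peaks (1.33%) did, with a ratio of 1.93 (adjusted p = 0.006). Without 185 crowded bins of 1 Mb that hold at least 10 peaks in some mouse list, the 12-week ratio fell to 1.25 and its call ended (permutation p = 0.083). The fullest bin, chromosome 12 from 115000001 to 116000000, held 72, 60 and 53 peaks in the normal, 8-week and 12-week lists. Protein-coding gene midpoints gave higher ratios than peaks in the same domains, at 1.94, 1.95 and 2.90. The rotations of peaks do not correct for gene density.

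Whether changed Foxa2 sites go with changed domains was tested by comparing Western-specific with shared peaks. At 8 weeks Western-specific peaks lay in sequence gained by domains less often than shared peaks, 2.12% against 4.54% (Fisher's exact test, odds ratio 0.455, 95% interval 0.316 to 0.656, adjusted p = 0.0001). In lost sequence the shares were 2.43% and 2.83% (adjusted p = 0.54). At 12 weeks Western-specific peaks lay in lost sequence less often than shared ones, 11.4% against 15.3% (odds ratio 0.711, 0.626 to 0.808, adjusted p = 1.8e-06). Sequence gained at 12 weeks held 30 Western-specific and 11 shared peaks (adjusted p = 0.54). Peaks found on normal diet and not at 12 weeks lay in lost sequence in 13.5% of cases. Lost sequence at 12 weeks was 301.2 of the 317.9 Mb of normal-diet domains. The 12-week test therefore cannot tell loss apart from lying in a normal-diet domain.

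Genes called in liver RNA were set against Foxa2 peaks within 20 kb of the gene. At 12 weeks, genes that fell had a Foxa2 site more often than other protein-coding genes, which include genes without expression in liver. A normal-specific peak stood by 91 of 243 such genes (37.4% against 15.0%, odds ratio 3.39, 95% interval 2.61 to 4.41, adjusted p = 2.3e-16), a shared peak by 27.2% (odds ratio 3.66, adjusted p = 8.8e-15) and a Western-specific peak by 29.6% (odds ratio 1.49, adjusted p = 0.013). With a window of 50 kb around the gene midpoint, which does not grow with the gene, the Western-specific odds ratio was 1.26 and did not pass (exact p = 0.11). Genes that rose at 12 weeks did not differ from other genes for normal-specific (odds ratio 1.11, 0.876 to 1.41), shared (1.21) or Western-specific peaks (0.979). With the midpoint window they did pass for normal-specific (1.28, exact p = 0.023) and shared peaks (1.40, p = 0.0087). Set directly against the genes that fell, the genes that rose had an odds ratio of 0.328 for normal-specific peaks (adjusted p = 3.7e-09) and 0.332 for shared peaks (adjusted p = 2.2e-07). Among genes at or above the 8-week expression minimum these were 0.362 and 0.370, and with the midpoint window 0.467 and 0.442. For Western-specific peaks the odds ratio was 0.656 (adjusted p = 0.045). That call ended with the midpoint window (0.892, 0.640 to 1.24, exact p = 0.50). The genes that rose include immune and matrix markers, and cell type was not controlled. These contrasts therefore cannot separate a link with Foxa2 sites from the cell type in which a gene is expressed.

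At 8 weeks both directions stood by normal-specific peaks more often than the 19.3% of other genes: 41.5% of genes that fell (odds ratio 2.97, adjusted p = 2.5e-11) and 33.7% of genes that rose (2.12, adjusted p = 4.9e-06). Shared peaks passed as well, for falling (2.79, adjusted p = 0.00057) and rising genes (2.05, adjusted p = 0.024). Rising and falling genes were not told apart (odds ratio 0.714, exact p = 0.12), and among genes with an absolute log2 fold change of at least 1 the rising genes no longer passed (1.56, p = 0.064). Western-specific peaks did not pass for rising (1.48, adjusted p = 0.08) or falling genes (0.784, adjusted p = 0.44). The genes not called include genes without expression in liver.

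Named genes show the pattern one by one. Beside Sqle, a normal-diet peak at chromosome 15, 59317122 to 59317321, within the gene's span, was absent from both Western lists, and the 12-week list had another peak within the gene, 59323736 to 59323799, absent from normal diet. The 2 peaks by Msmo1 and the 2 by Enho were likewise normal-specific at both times. A peak within Abcg8 and less than 20 kb from Abcg5 (chromosome 17, 84689465 to 84689716) was shared by normal diet with both Western lists, as was 1 by Scd1 (chromosome 19, 44380167 to 44380366). Around Cd36 the only peaks were Western-specific, 1 at 8 weeks and 3 at 12 weeks. Cidec had 1 shared peak at 12 weeks (chromosome 6, 113427518 to 113427717), and neither Cidea nor Pnpla3 nor Pnpla5 had a peak in any list compared at 12 weeks.

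**Figure D4:**
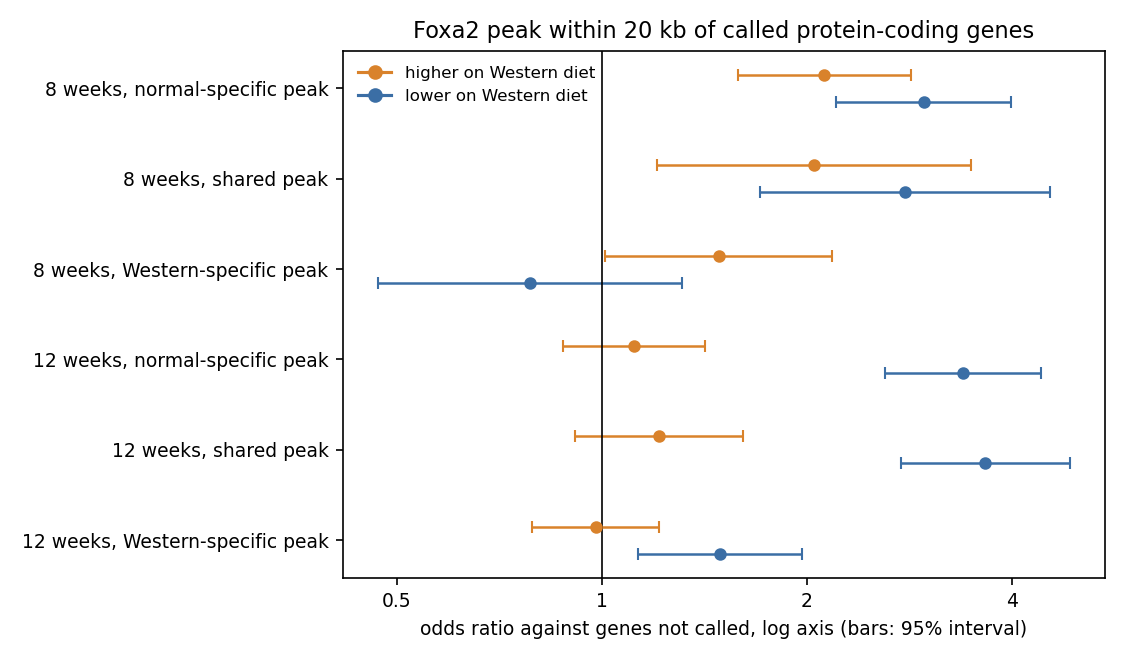
Points give the odds ratio, on a log axis, that a called gene rather than a gene not called has a Foxa2 peak of each class within 20 kb, for genes higher (orange) and lower (blue) on Western diet, with 95% intervals. At 12 weeks the genes that fell lie at 3.39 and 3.66 for normal-specific and shared peaks, and the genes that rose at 1.11 and 1.21.

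Called genes were also placed in the domains by their midpoint. Genes that fell at 8 weeks lay in sequence kept by domains more often than other genes, 31.7% against 21.8% (odds ratio 1.66, 95% interval 1.22 to 2.28, adjusted p = 0.026), a call that ended among genes with an absolute log2 fold change of at least 1 (1.46, exact p = 0.16). At 12 weeks 145 of 499 rising genes (29.1%) lay in lost sequence against 23.8% of other genes (odds ratio 1.31, 1.08 to 1.59, adjusted p = 0.047). Falling genes stood at 26.7%, and rising against falling genes gave 1.12 (0.796 to 1.58, exact p = 0.54). Since 301.2 of the 317.9 Mb of normal-diet domains counted as lost, neither comparison can tell loss apart from lying in a normal-diet domain. Cidea, Pnpla3, Pnpla5, Slc2a4, Ly6d, Mas1, Mpped1, Lcn2, Trem2 and Col1a1 overlapped normal-diet domains that were absent at 12 weeks, and so did the falling genes Spatc1l, Slc13a2, Rab11fip4, Irs2, Foxa3, Lss and Srebf2. Abcc4 lay in a domain gained at 8 weeks. No other class passed the threshold.

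In human liver the lamin B1 domains covered 479.8 Mb in 1345 domains without disease (hg19), 714.5 Mb in 1457 domains in mild NAFLD and 709.6 Mb in 1616 domains in severe NAFLD. Mild disease kept 304.8 Mb (63.5%) of the normal sequence and severe disease 302.6 Mb (63.1%). The overlap with normal had a Jaccard index of 0.343 in mild and 0.341 in severe disease, and mild and severe lists shared 459.6 Mb with an index of 0.477. In mild disease 599 domains had no normal counterpart and in severe disease 726. The longest domain lost in mild disease lay on chromosome 11, 43880001 to 45309999, and the longest gained on chromosome 19, 27730001 to 29029999. The segment on chromosome 17, 78650001 to 79449999, was among the 5 longest lost in both. In severe disease the longest lost was chromosome 12, 109460001 to 110559999, and the longest gained chromosome 9, 101010001 to 102419999. A gain on chromosome 17 was found in both, from 71330001 to 72489999 in mild and from 71310001 to 72409999 in severe disease. Human regions are given by position alone, and the shortest domain listed differs between groups, at 110, 200 and 120 kb.

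Human Foxa2 lists held 6623 peaks without disease, 4578 in mild and 9644 in severe NAFLD. These lists also differ in form: mild peaks go down to 1 bp with a median of 67 bp, while normal and severe peaks are at least 200 bp long. Of the mild peaks 1159 (25.3%, Wilson 95% interval 24.1 to 26.6) overlapped a normal peak. Of the severe peaks 486 (5.04%, 4.62 to 5.49) did, and 455 (4.72%) overlapped a mild peak. Rotated lists gave means of 4.30, 12.1 and 6.92 peaks. The severe peaks were crowded: 46.6% of them stood in the 236 bins of 1 Mb with at least 10 peaks in some human list, against 27.6% of normal and 27.3% of mild peaks. The bin on chromosome 4 from 190000001 to 191000000 was the fullest in each list, with 64, 73 and 117 peaks. Of the severe peaks shared with normal, 78.6% stood in crowded bins, and without those bins 2.02% of severe peaks were shared with normal and 1.94% with mild.

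Foxa2 peaks inside domains of the same group made up 16.2% of normal peaks, a ratio of 0.973 to rotation (adjusted p = 0.61). In mild disease they made up 21.3%, below rotation (ratio 0.848, adjusted p = 0.006), and in severe disease 29.4%, above it (ratio 1.18, adjusted p = 0.006). Without crowded bins the normal ratio was 0.868 and passed (permutation p = 0.001).

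Peaks specific to disease were compared with shared peaks for the domains gained or lost. In mild disease 13.1% of specific peaks lay in gained sequence against 6.47% of shared peaks (odds ratio 2.17, 95% interval 1.69 to 2.80, adjusted p = 1.8e-09), and in severe disease 16.1% against 9.05% (odds ratio 1.93, 1.41 to 2.65, adjusted p = 3.0e-05). Peaks found only without disease lay in sequence gained in mild disease in 12.0% of cases, and against them the mild odds ratio was 1.11 (exact p = 0.13), so the mild call ended. In severe disease the odds ratio against such peaks was 1.69 (exact p = 3.9e-26), while without crowded bins the comparison with shared peaks gave 1.74 (p = 0.086). Comparisons with peaks found only without disease count neighbouring peaks as independent. Neither bin resampling nor removal of crowded bins was run for them. In lost sequence specific peaks were fewer, 6.79% against 9.58% in mild (odds ratio 0.687, adjusted p = 0.0036) and 6.91% against 11.7% in severe disease (odds ratio 0.559, adjusted p = 0.00032), and without crowded bins these became 1.04 and 1.16, neither past the threshold. Against peaks found only without disease they were 0.991 and 0.983, and neither passed.

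Sequence kept by domains showed differences too, and their direction in severe disease depended on the comparison. Mild-specific peaks lay in kept sequence in 11.1% of cases against 6.21% of shared peaks (odds ratio 1.89, adjusted p = 2.5e-06). The mild odds ratio was 2.86 without crowded bins (exact p = 1.5e-09) and 1.2 against peaks found only without disease (exact p = 0.013). Severe-specific peaks did so in 1216 of 9158 cases against 102 of 486 (odds ratio 0.576, adjusted p = 1.5e-05), a call that ended with resampled 1 Mb bins (0.602, 0.293 to 1.70). It turned to 1.89 without crowded bins (exact p = 0.083) and to 1.78 against peaks found only without disease (exact p = 5.6e-26). That last p-value counts neighbouring peaks as independent, with no check by bins. The difference between mild and severe disease did not pass (adjusted p = 0.17).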

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

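The test of difference between durations was chosen only after the results were seen. For the 148 genes called at both times, the 8- and 12-week log2 fold changes in the authors' deposited tables were compared with standard errors implied by each likelihood ratio, and 13 genes differed after Benjamini-Hochberg adjustment. The implied errors are approximate, and values per animal were not used. The 6 genes of opposite sign were bound to pass, since each had been called at both times. Their adjusted p-values therefore add no support for a change with duration.

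Differences are given as 12 weeks minus 8 weeks on the log2 scale, from the authors' deposited tables. Moxd1 differed by -8.78, from 3.73 to -5.05, Scara5 by -3.11, Foxq1 by -3.04, Eif4ebp3 by -2.78 and the glucocorticoid-induced gene Fkbp5 by -2.56, and these 5 turned from higher to lower. Gstm3 turned the other way, with a difference of 2.35 (adjusted p = 2.2e-10). Itih5 and Abca8a were lower at both times and further down at 12 weeks, by -1.24 and -1.23. The sterol pathway gene Mvd was lower at both times and less so at 12 weeks, a difference of 1.37. Rgs16, Tceal8, Anxa2 and 2010003K11Rik were higher at both times and more so at 12 weeks, by 2.91, 2.02, 1.66 and 1.65.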

How the results depend on the processing

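Removal of crowded bins or muscle transcripts, the 8-week expression minimum, human domains of at least 200 kb, 200 bp peaks, equal list lengths, the tested-gene background, comparison with the other direction or with normal-specific peaks, and the 50 kb midpoint window were tests chosen only after the results were seen; the rest were planned. Of 294 alternatives 219 (74.5%) kept the result, 13 lost a call, 9 gained one and 27 moved a value. The other 26 turned an odds ratio across 1, many of them not past the threshold on either side. The cause was not tested. Here "past" means an unadjusted p under 0.05, in the reported result and the alternative alike. Counts and covered lengths were scored as kept within 1.5 times the reported value. Some of the 219 could not have changed. A minimum domain length of 100 kb altered no covered length in mouse or human. Removal of muscle transcripts left 390 of 395 genes at 8 weeks and all 761 at 12 weeks. The share kept is therefore no measure of robustness for domain lengths. No paired analysis was possible because mice and people belong to single groups and the deposited values are not per sample. DESeq2, no count filter, a replicate block, each replicate left out, another pseudocount and the better-scoring part of each peak list were not run, since they need values per sample or scores that were not used here.

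Called genes at adjusted p under 0.01 numbered 254 (8 weeks) and 376 (12 weeks), and 173 at 8 weeks with a log2 fold change of at least 1 in size. With the tested-gene background 7 lists passed at 8 weeks.

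Percent of peaks shared: 8-week with normal diet, 18.0 (50% covered), 17.4 (200 bp peaks), 15.7 (no crowded bins). 12-week with normal diet, 38.0 (equal lengths), 20.3 (no crowded bins). 12-week with 8-week, 7.40 (50% covered), 9.28 (within 500 bp), 16.6 (equal lengths), 6.84 (no crowded bins). Mild with normal, 24.0 (50% covered), 26.9 (500 bp), 23.9 (200 bp), 22.3 (equal lengths). Severe with normal, 3.67, 6.44, 3.56, 6.44 and, without crowded bins, 2.02. Severe with mild, in the same order, 3.11, 6.18, 3.35, 7.34 and 1.94.

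Without crowded bins, the ratio of 12-week peaks in domains was 1.25 and no longer passed, and that of normal human peaks was 0.868 and passed. Odds ratios without crowded bins were 1.04 (mild, lost) and 1.16 (severe, lost), both turned above 1, and 1.74 (severe, gained), no longer past. Against normal-specific peaks 0.991 (mild, lost), 1.11 (mild, gained) and 0.983 (severe, lost) did not pass, nor did 0.584 (severe, lost) with resampled bins. In kept sequence severe peaks turned to 1.89 without crowded bins (not past) and 1.78 against normal-specific peaks (past), and 0.602 with resampled bins was no longer past; 8-week peaks gave 1.02 within 500 bp (turned) and 0.851 against normal-specific peaks (past). In gained sequence 12-week peaks turned to 1.2 against normal-specific peaks.

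For genes near Foxa2 peaks, log2 fold changes of at least 1 gave 1.85 (8 weeks, rising, Western-specific, now past) and 1.56 (rising, normal-specific, no longer past). Against the other direction, 8-week rising genes turned to 0.714 (normal-specific) and 0.735 (shared), and falling genes gave 1.40 and 1.36, none past; 12-week rising genes gave 0.656 (Western-specific), and turned to 0.328 (normal-specific) and 0.332 (shared), all past. With the midpoint window 12-week rising genes gave 1.28 (normal-specific) and 1.40 (shared), both past, and falling genes 1.26 (Western-specific), no longer past. Values near 1 that turned and passed on neither side were Western-specific 1.28 (100 kb) and 1.22 (midpoint) for 8-week falling genes, Western-specific 1.09 (100 kb), 1.03 (fold changes of at least 1) and 1.12 (midpoint) and normal-specific 0.981 (5 kb) for 12-week rising genes.

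For genes in domains, the other direction gave 0.532 (8 weeks, rising, kept, past, but adjusted p = 0.059) and 1.12 (12 weeks, rising, lost, not past). Merged domains gave 1.96 (8 weeks, falling, gained, past), fold changes of at least 1 gave 1.46 (8 weeks, falling, kept, not past) and whole gene bodies 15.9 (12 weeks, falling, gained, past). Turned, with neither side past, were 8-week rising genes in lost (1.60 for fold changes of at least 1, 1.61 against the other direction) and gained sequence (1.10 merged, 1.65 for fold changes of at least 1), 12-week rising genes in gained (0.486, other direction) and kept sequence (0.970, gene bodies), and 12-week falling genes in lost (0.892, other direction) and kept sequence (0.827 gene bodies, 0.996 merged, 0.932 other direction).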

Other observations

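All tests in this part were chosen only after the results were seen. Interferon-stimulated genes rose at both times: 10 of 41 were higher at 8 weeks in the authors' deposited table (odds ratio 19.7, adjusted p = 3.4e-09), with Ifit1 at 1.54 and Xaf1 at 1.53, and 27 were higher at 12 weeks (odds ratio 66.5, adjusted p = 3.5e-30). The 12-week table reaches lower-expressed genes, and 17 of the 27 lie at or above the 8-week expression minimum. At 12 weeks Ifi27l2a stood at 3.06, the chemokine gene Cxcl9 at 2.99, Oas1a at 2.32 and Isg15 at 1.69 in the authors' deposited table. Neutrophil genes were higher in 4 of 17 cases at 12 weeks (adjusted p = 0.0031): S100a9 at 5.80, Ngp at 5.18, Lcn2 at 4.13 and Cebpe at 2.41 in the authors' deposited table. At 8 weeks 1 neutrophil gene was listed (adjusted p = 0.33), 2 of the 4 at 12 weeks lie at or above the 8-week minimum, and Lcn2 is also an acute phase gene of hepatocytes.

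Glutathione genes fell at 8 weeks, 9 of 26 in the authors' deposited table (odds ratio 30.3, adjusted p = 1.8e-09), among them Gsta2 at -1.62, Gstm3 at -1.54, Gstt2 at -1.40 and Mgst3 at -1.38. At 12 weeks 3 were higher and 2 lower (adjusted p = 0.0027), led by Gstt3 at -1.54 and Gstp3 at 1.49 in the authors' deposited table, and these paralogs can share reads. Protein genes of the mitochondrial genome were not listed at 8 weeks, and 4 of 13 were higher at 12 weeks (adjusted p = 0.0016): mt-Nd6 at 1.63, mt-Co2 at 1.55, mt-Atp6 at 1.53 and mt-Co3 at 1.49 in the authors' deposited table. The difference between the mild and severe groups in the log2 odds ratio for peaks in kept domains was -1.70 and did not pass after adjustment.

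The 4 muscle transcripts that fell at 8 weeks (Acta1, Myh4, Ttn and Atp2a1) may come from muscle tissue taken with some normal-diet livers, which would make them vary widely between animals. The lowest of their implied standard errors was 1.5, above the highest of the other 391 called genes, 1.14. Eno3, another muscle gene lower at 8 weeks (5 of 25, adjusted p = 0.00016), did not share this, at -1.09 in the authors' deposited table. Its implied error was 0.323, under the 95th percentile of the others, 0.466. The implied error comes from the fold change and the likelihood ratio. It is no direct measure of spread between animals, so it cannot decide. At 12 weeks 1 muscle gene was higher (adjusted p = 0.64). A change in liver itself was not tested and stays open, since values per animal were not used.

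Most Foxa2 peaks stood in 1 list, which may reflect how the lists were made as much as binding. Different peak widths are argued against as the cause: allowing 500 bp raised sharing by at most 1.31 times. Weak peaks near the calling threshold remain a candidate source, and a change of binding with diet or disease stays open: the first of 10 parts of a list was shared more often than the last in 12 of 12 ordered pairs. The order is not documented. Longer peaks tend to come first, but only weakly in the human normal and severe lists (Spearman correlation of position with length -0.157 and -0.169). With every peak set to 200 bp the same held in 12 of 12. In the first part of the severe list, 75.2% of peaks were not shared with normal and 77.5% not with mild. Place in the list alone therefore does not account for most unshared severe peaks. Place is not known to measure peak strength, so weak peaks are not excluded as their source. Among severe peaks shared with normal, 78.6% stood in crowded bins against 46.6% of all severe peaks, so crowded sequence is a candidate source of much of that overlap.

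The 12-week lamin B1 list covered little sequence. Fewer domains passing the same threshold is a candidate explanation, and a loss of lamina contact that raises genes is another. They cannot be told apart: that 95.1% of its bases lie inside normal-diet domains is what either would give, and the odds ratio of lost domains for rising against falling genes was 1.12 (95% interval 0.796 to 1.58, exact p = 0.54), too wide to decide. Lost sequence takes in nearly all normal-diet domain sequence, so this odds ratio could not test loss apart from position in those domains. Depth per sample is unknown, which keeps both open. The second candidate also takes the listed regions to touch the lamina, which was not tested. Those regions lay in gene-dense sequence, with 17.9 protein-coding gene midpoints per Mb inside normal-diet domains against 6.79 outside.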
